A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

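The labels describe rice seedlings (Oryza sativa, Japonica variety Zhonghua 11, ZH11) at the 4-leaf stage, from which the above-ground parts were taken. Plants were kept under normal watering or under drought until all leaves had rolled, and unstressed plants were collected at the same time. RNA was sequenced from ZH11, an OsbZIP23 mutant and an OsbZIP23 overexpressor, each with and without drought. Chromatin bound by OsbZIP23 was precipitated with a rabbit polyclonal antibody from seedlings fixed in 1% formaldehyde, with DNA sheared to 100 to 500 bp. That assay (ChIP-seq) covered ZH11 under normal growth, ZH11 under drought and the overexpressor under normal growth. Each of the 9 groups had 1 library, so no group had replicates.

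The deposited RNA tables give expected counts per gene in a column of read numbers, per the file headers, and FPKM (fragments scaled by gene length and library size) beside them. The authors' read numbers came in steps of 0.5; between 13.9% and 16.8% of the genes in a table ended in 0.5. They were rounded for the count models. The authors' FPKM values served only as a check. Read number over FPKM gave an implied gene length, scaled by library. In each of the other tables, 88.3% to 91.5% of genes came within 1% of their implied length in ZH11 normal. The deposited peak lists give, per the file headers, the position and summit of each peak, its tag counts, its score (-10 log10 of the p value) and its fold enrichment, a ratio of tags to the local background. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, TopHat2 2.0.8 and edgeR 3.6.0 were used for RNA, and peaks came from MACS 1.4.2. The role of edgeR 3.6.0 in the authors' tables, the aligner of the ChIP reads, the genome build and the annotation were not given in the sources used here. Peaks were called by the authors without a control library, at a p cutoff of 1e-05, a local background window of 10000 bp and 1 tag kept per position. The headers state a genome size of 2.7 Gb, while the peaks span 374 Mb of chromosome.

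The 56001 lines of the RNA tables gave 55986 genes after 15 repeated names were summed. Gene levels are read numbers scaled to library size (CPM) after scaling by the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. The factors ran from 0.754 for the mutant under drought to 1.21 for the mutant under normal growth. Gene tests used edgeR's quasi-likelihood fit with additive terms for genotype and stress over all 6 libraries. filterByExpr by stress group left 21409 tested genes. The fit had 2 residual degrees of freedom, 4.02 prior degrees of freedom and a common dispersion of 0.0954. Any dependence of the drought effect on genotype sits in its error. A gene passed at an adjusted p (Benjamini-Hochberg) under 0.05, 2-sided, and "rose", "fell" and "changed" are used only for such genes. DESeq2 1.42.0 was the other count model. Log2 fold changes carry the standard error (SE) of the fit.

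Contrasts of 1 library against 1 library were not tested. They are log2 ratios of TMM-scaled CPM plus 0.5, over genes with at least 10 reads in either library. Ratios of named genes carry exact (Clopper-Pearson) 95% intervals from their read counts. Intervals and floors cover counting error only, since reads were not counted by molecule and plants were not replicated. Where one side had 0 reads, the ratio is given as a lower bound, with a floor of 3 counts over the group.

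Gene lists and the naming rule were fixed before the data were examined, together with the tests and most alternatives. There were 16 lists of loci and 17 lists matched on words in the tables' gene descriptions. A locus listed as Rab25 was left out because the tables describe it as a DNAJ protein. Of the 139 loci that remained, 2 were absent from the tables. Locus symbols came from general knowledge of the rice literature and not from the tables. Lists for core histones, peroxidases and lipid transfer proteins matched 0 genes. Lists with at least 3 tested members, 27 of them, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Adjusted p values run over the 27 lists of one comparison. The test was repeated with the correlation estimated from the data. That repeat rests on the 2 residual degrees of freedom of the fit. An adjusted p under 0.05 was hardly within its reach, so a missing call there decides little. For single-library contrasts the percentile of a list's median among 10000 random gene lists of equal size is given. The random lists were matched in 20 bins on mean CPM over all RNA libraries, not on the level in the 2 libraries compared. Named genes for drought and genotype have a mean of at least 10 CPM and the largest log2 fold changes. There are 10 each way for drought and 8 each way for genotype. They had to go the same way in all 3 genotypes (drought) or in both conditions (genotype). For single-library contrasts, the rule picked 5 each way with at least 50 reads, and only some of these are named below. Genes described as transposons, reverse transcriptases, DNA/RNA polymerases, ribonuclease H-like, DNAse I-like or ribosomal RNA were left out of this naming. In each fixed list the 4 passing members with the largest changes are named. Members named beyond these were chosen after their values were seen.

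Peak lists were compared by overlap of at least 1 bp, beside 100 random placements of the same peaks on the same chromosomes. Their shares carry exact 95% intervals over peaks. Genes with a peak in the promoter, motif content and the expression of bound genes were planned but not run, since they need a genome sequence and gene positions of the same build. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for peaks, summaries and plots.

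The gene test was tried on made-up tables with known changes, 50 genes per fold change. Every gene had the common dispersion, and only the chosen genes differed between libraries, a simpler setting than the real data. For drought the test recovered 16% of genes at 2-fold, 96% at 4-fold, 100% at 8-fold and 98% at 16-fold. It made 4 false calls among 20948 tested genes. For the mutant it recovered 6%, 66%, 100% and 100% at the same folds, with 3 false calls among 20900. For the overexpressor it recovered 6%, 64%, 98% and 100%, with 4 false calls among 20953. A phosphatase list shifted 4-fold was called by camera (adjusted p = 2.9e-41) and 0 of 26 unshifted lists were. Genes were drawn independently of each other there, so false calls of lists with correlated members were not checked. Background means of 500 simulated peaks were recovered from their tag counts and scores with a largest error of 0.00875%, which checks that calculation only. Alternatives covered scaling, filters, the other count model, dropped model terms, dropped libraries, pseudocounts, the set-test correlation and peak thresholds. Leaving out both overexpressor libraries was added after the data were seen.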

Results

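OsbZIP23 is a basic leucine zipper transcription factor that acts in the response of rice to abscisic acid (ABA), the hormone of drought. The series asked how it regulates ABA synthesis, ABA signalling and drought-resistance genes. Transcript levels were measured in 6 RNA libraries, 1 for each of ZH11, the OsbZIP23 mutant and the OsbZIP23 overexpressor under normal growth and under drought. OsbZIP23 binding was measured in 3 ChIP-seq libraries, from ZH11 under normal growth, ZH11 under drought and the overexpressor under normal growth. Total reads were 12.2 M for ZH11 normal, 13.5 M for ZH11 drought, 12.2 M for mutant normal, 9.48 M for mutant drought, 10.8 M for overexpressor normal and 10.0 M for overexpressor drought. Between 29340 genes (mutant drought) and 33599 genes (mutant normal) had reads. The 4 genes with the most reads, none with a description, took from 7.12% of reads in mutant normal to 19.5% in overexpressor drought. MACS used 6.15 M, 7.14 M and 6.05 M tags for ZH11 normal, ZH11 drought and overexpressor normal. Without replicates, errors given as SD run over the 3 genotypes of one stress state. On log2 CPM, the first principal component, which separated drought from normal libraries, held 83.6% of the variance and the second 9.14%.

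OsbZIP23 itself (LOC_Os02g52780, described in the tables as ABRE binding factor 4) was read in every library. It had 32.5 CPM in ZH11 normal and 479.6 CPM in ZH11 drought, 14.8-fold more (95% interval 13.4–16.3). In the mutant it had 11.9 CPM under normal growth and 158 CPM under drought, a 13.3-fold difference (11.4–15.7). These mutant levels were 36.5% (30.5–43.6) of ZH11 under normal growth and 33.0% (30.9–35.2) under drought. In the overexpressor it had 1325 CPM under normal growth, 40.8-fold the ZH11 level (37.1–45.0), and 457 CPM under drought, 0.954 of the ZH11 level (0.917–0.992). The drought ratio in the overexpressor was 0.345 (0.334–0.357), the other way from both other genotypes. In the additive fit OsbZIP23 passed in no comparison: drought log2 fold change 2.42 (SE 1.35, adjusted p = 0.173), mutant -1.56 (SE 1.23, adjusted p = 1.00) and overexpressor 3.53 (SE 1.57, adjusted p = 0.942).

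**Figure D1:**
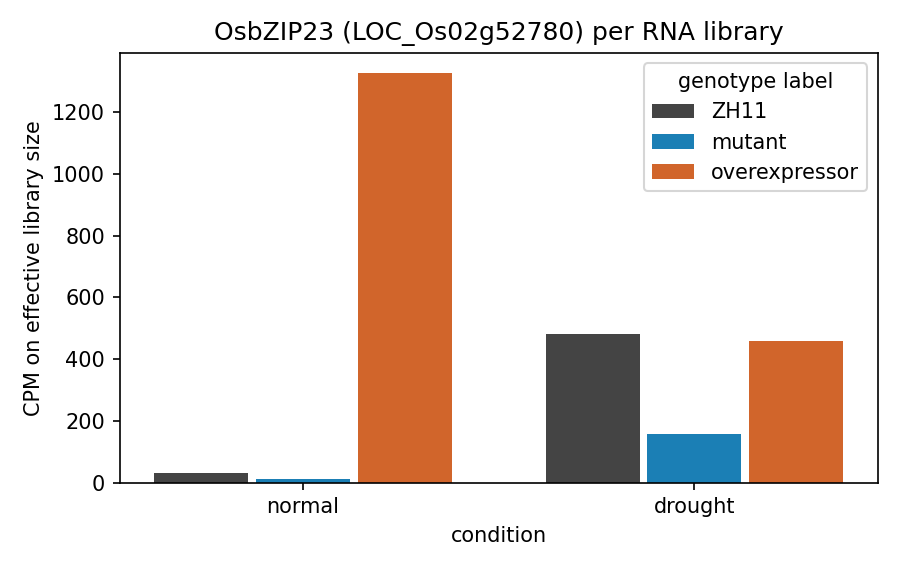
Bars give the OsbZIP23 level in CPM (vertical axis, from 0) for each genotype under normal growth and under drought, 1 RNA library per bar. The overexpressor stands at 1325 CPM under normal growth, while under drought it stands at 457 CPM beside 479.6 CPM in ZH11.

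The drought comparison asks which transcripts change when water is withheld, over the 3 genotypes together. Transcripts of late embryogenesis abundant (LEA) proteins and dehydrins, which protect drying cells, had the largest median of the fixed lists. The dehydrin gene Rab16A rose 3542-fold (interval 2979–4246), from 3.20 ± 0.886 to 11121 ± 1818 CPM (SD, n = 3). Isocitrate lyase (LOC_Os07g34520), an enzyme of the glyoxylate cycle, rose 3645-fold (2086–7054), from 0.289 ± 0.238 to 1191 ± 925 CPM (SD, n = 3). In the other direction, a small subunit of Rubisco (RbcS, LOC_Os12g17600), which fixes carbon dioxide, fell from 10109 ± 2062 to 108 ± 88.8 CPM (SD, n = 3). In all, 11475 of 21409 genes changed in edgeR, 5579 up and 5896 down, and 12989 had an unadjusted p under 0.05. DESeq2 called 11175, 5722 up and 5453 down. Under total count scaling the calls were 4024 up and 7328 down, and the median log2 fold change of all genes moved by -0.39. Without the ZH11 normal library 5238 genes changed, and without the ZH11 drought library 4898 did. Over the 10 splits of the 6 libraries into 3 and 3, the real one gave 11475 calls and the highest other gave 0. The other splits leave much of the drought difference in the residual, so few calls were possible there. The 10 splits are also too few for a share under 0.05, so this comparison decides nothing.

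Of the 10 largest rises, 6 genes had a description. LOC_Os02g26720, of an inositol phosphate kinase family, rose 17475-fold (3136–690269) with 1 read over the normal libraries. LOC_Os04g52110, a LEA protein, rose 7800-fold (2159–64414). LOC_Os12g27830, hydroxysteroid dehydrogenase 1 of oil bodies, rose 8156-fold (1463–322184). LOC_Os03g02050, of the lipid-transfer and seed storage albumin family, rose 9955-fold (1786–393266), also with 1 read. LOC_Os03g04080, a transcription activator-related gene, rose 4410-fold (2323–9645), from 0.223 ± 0.0667 to 974 ± 252 CPM (SD, n = 3). Isocitrate lyase was the sixth. The other 4 had no description, among them LOC_Os11g32890 and LOC_Os04g33150; the latter had 0 reads under normal growth and rose at least 931-fold. Of the 10 largest falls, 6 had a description. Terpene synthase 21 (LOC_Os08g04500) fell 453-fold (238–990), from 142 ± 17.1 to 0.357 ± 0.299 CPM (SD, n = 3). A terpenoid cyclase (LOC_Os02g36210) fell 523-fold (224–1613). A receptor kinase related to pathogenesis-related protein 5 (LOC_Os01g02780) fell 1273-fold (228–50311), and a receptor of the family that senses bacterial EF-Tu (LOC_Os02g39660) fell 691-fold (124–27321), each with 1 read over the drought libraries. A lectin kinase (LOC_Os09g16950) fell 338-fold (172–784) and LOC_Os01g74160, a gene of unknown function, fell 1505-fold (515–7300). The 4 without a description included LOC_Os04g39320 and LOC_Os01g09190. All 20 passed under each of the 12 alternatives, with adjusted p from 3.7e-04 to 7.0e-04 as first fitted. That they went the same way in 3 of 3 genotypes was a condition of naming.

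Of 9 tested clade A protein phosphatases 2C (PP2C), which hold ABA signalling back, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 3.68. OsPP2C51 rose by 8.02 (SE 0.73), OsPP2C68 by 6.01 (SE 0.55), OsPP2C49 by 4.30 (SE 0.72) and OsPP2C30 by 4.27 (SE 0.51) on the log2 scale. The list was called by camera (adjusted p = 1.1e-04; adjusted p = 0.511 with an estimated correlation). Of 10 SnRK2 kinases, which these phosphatases inhibit, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 0.0335; adjusted p = 0.511 with an estimated correlation). SAPK1 rose by 3.76 (SE 0.40), SAPK4 by 3.61 (SE 0.25), SAPK9 by 2.57 (SE 0.23) and SAPK10 by 2.07 (SE 0.24), while SAPK7 fell by 1.88. Of 7 tested bZIP factors related to OsbZIP23, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 0.0705). OsbZIP12 rose by 4.11 (SE 0.37), OsbZIP40 by 3.10 (SE 0.25) and OsbZIP46 by 3.03 (SE 0.44), while OsbZIP62 fell by 3.15 (SE 0.44). This list passed without ZH11 normal (adjusted p = 0.0246), ZH11 drought (0.0476), mutant normal (0.0284), overexpressor normal (0.0157) or overexpressor drought (0.0133).

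Of 8 tested ABA synthesis genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone), with a median of 1.08 (camera adjusted p = 0.576). The family of 9-cis-epoxycarotenoid dioxygenases (NCED), which cleave carotenoids at the limiting step, went both ways. OsNCED4 rose by 8.15 (SE 1.14) and OsNCED3 by 3.8 (SE 0.57), while OsNCED1 fell by 6.94 (SE 0.90), from 1279 ± 219 to 21.9 ± 30.2 CPM (SD, n = 3). OsABA2, an alcohol dehydrogenase of the later steps, fell by 2.29 (SE 0.36). Of 3 ABA hydroxylases, which break ABA down, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.794), OsABA8ox3 by 2.53 (SE 0.57). Of 13 listed ABA receptors 4 had enough reads to be tested; 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.407), LOC_Os03g18600 by 3.75 (SE 0.36).

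All 13 tested LEA and dehydrin genes rose (13 adjusted over the list alone), with a median log2 fold change of 10.62, or 10.47 with OsEm1 at its bound. OsEm1 had 0 reads under normal growth and rose at least 214-fold. Beside Rab16A, OsLEA3-1 rose 3056-fold (2449–3867), Rab16B by 11.38 (SE 0.77) and Rab16D by 11.23 (SE 0.46) on the log2 scale. The list was called by camera (adjusted p = 1.1e-10; adjusted p = 0.511 with an estimated correlation). Of 18 tested stress transcription factors, 11 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 3.20 (camera adjusted p = 0.00236; adjusted p = 0.550 with an estimated correlation). OsHOX24 rose by 9.65 (SE 0.86), ZFP182 by 9.31 (SE 0.56), OsDREB1C by 6.63 (SE 0.76) and ZFP252 by 6.29 (SE 0.31). Those that fell were DST, a zinc finger factor of stomatal control, by 4.09, OsWRKY45, a factor of disease resistance, by 3.85, and OsMYB48-1 by 2.70. Of 12 genes for proline, trehalose and raffinose, which act as compatible solutes, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 0.0438; adjusted p = 0.511 with an estimated correlation). Galactinol synthase OsGolS2 rose by 7.76 (SE 0.43), raffinose synthase RafS by 4.41 (SE 0.38), OsP5CS2 of proline synthesis by 4.05 (SE 0.66) and OsGolS1 by 3.96 (SE 0.30). Of 8 antioxidant enzymes 3 rose and 3 fell (3 and 3 adjusted over the list alone). Catalase CatA fell by 5.55 (SE 1.01) and CatC by 1.75 (SE 0.42), while CatB rose by 3.07 (SE 0.37) and the superoxide dismutase SodCc2 by 3.29 (SE 0.36). The median of this list was -0.38 and the mean -0.17, while camera put it upward (adjusted p = 0.854).

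Of 14 tested photosynthesis genes, 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -4.61 (camera adjusted p = 3.6e-06; adjusted p = 0.511 with an estimated correlation). Beside RbcS LOC_Os12g17600, which fell by 6.87 (SE 0.82), RbcS LOC_Os12g19470 fell by 5.80, RbcS LOC_Os12g19381 by 5.78 and the light-harvesting gene Lhcb LOC_Os07g37240 by 5.37 (SE 0.51). Rubisco activase (Rca) did not pass, with a log2 fold change of -0.12. The 3 genes of senescence and chlorophyll breakdown rose (3 adjusted over the list alone), with a median of 3.95 (camera adjusted p = 0.0116; adjusted p = 0.511 with an estimated correlation). SGR rose by 5.09 (SE 0.34), OsNAP by 3.95 (SE 0.41) and NYC1 by 2.49 (SE 0.37). Of 3 tested cell cycle genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.576). The mitotic cyclins CycB2;1 and CycB1;1 rose by 2.97 and 2.03, while the kinase CDKB1;1 fell by 1.76. Of 6 housekeeping genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.580), GAPDH by 1.4 (SE 0.24). Among 4 listed root markers only Lsi1, a silicon channel, had enough reads; its log2 fold change was -0.43 (SE 0.35, adjusted p = 0.323). The meristem marker OSH1 had too few reads to be tested.

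Among lists matched on gene descriptions, camera called 5 under drought. Of 51 LEA and dehydrin genes, 31 rose and 8 fell (31 and 8 adjusted over the list alone), with a median of 1.61 (camera adjusted p = 9.7e-06; adjusted p = 0.511 with an estimated correlation). Of 64 heat shock proteins and chaperones, which keep proteins folded, 40 rose and 4 fell (41 and 4 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 3.6e-06; adjusted p = 0.591 with an estimated correlation). The small heat shock proteins LOC_Os04g36750 and LOC_Os03g14180 rose by 10.70 and 8.83. Of 57 NAC factors, 25 rose and 6 fell (25 and 6 adjusted over the list alone), with a median of 1.21 (camera adjusted p = 0.00382; adjusted p = 0.667 with an estimated correlation); LOC_Os02g34970 rose by 6.17 and SNAC1, a drought-tolerance factor of guard cells, by 5.20. Of 32 bZIP factors, 17 rose and 4 fell (19 and 4 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 0.0157; adjusted p = 0.511 with an estimated correlation); LOC_Os11g05640 rose by 6.79 and LOC_Os12g40920 fell by 6.29. Without the mutant drought library the bZIP list had adjusted p = 0.0548. Of 348 ribosomal protein genes, 17 rose and 141 fell (16 and 130 adjusted over the list alone), with a median of -0.90 (camera adjusted p = 5.1e-06; adjusted p = 0.744 with an estimated correlation); LOC_Os05g49320, a protein L12, fell by 4.55 and LOC_Os01g59950 rose by 4.20.

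The other description lists were not called. Of 9 genes described as chlorophyll a/b binding, 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0859, and 0.0476 without the ZH11 drought library), opposite to the photosynthesis list. LOC_Os01g14410 rose by 4.52 and LOC_Os02g16560 by 3.88; that description is shared by light-harvesting proteins and by early light-induced proteins, which appear under stress. Of 57 PP2C genes of all clades, 21 rose and 13 fell (21 and 14 adjusted over the list alone; camera adjusted p = 0.244). Of 10 expansins, which loosen cell walls, 2 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.321), LOC_Os10g40720 at -6.30 and LOC_Os06g50960 at -5.85 among the falls. Of 64 WRKY factors, 17 rose and 13 fell (17 and 13 adjusted over the list alone; camera adjusted p = 0.403), LOC_Os12g02470 at -6.07. Of 58 glutathione S-transferases, 15 rose and 20 fell (15 and 22 adjusted over the list alone; camera adjusted p = 0.794). Of 176 cytochromes P450, 47 rose and 71 fell (48 and 71 adjusted over the list alone; camera adjusted p = 0.244), LOC_Os06g45960 at -10.80 and LOC_Os01g72270 at 10.22. Of 6 terpene synthases, 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.914). Of 6 genes in the AP2/ERF list, 1 rose and 3 fell (2 and 3 adjusted over the list alone); its median was -0.31 and its mean 0.26, and camera put it downward (adjusted p = 0.914). Of 2 aquaporins, 1 rose (1 adjusted over the list alone), LOC_Os10g35050 by 9.61.

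**Figure D2:**
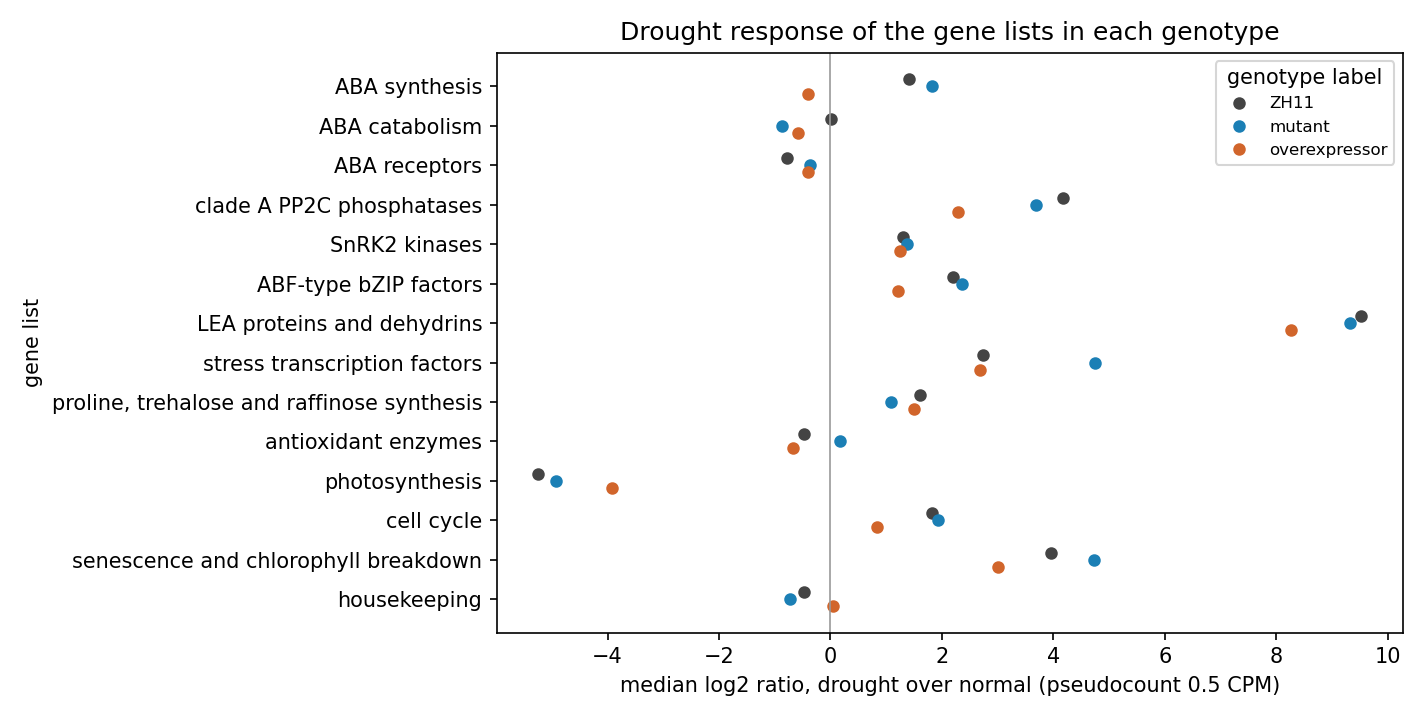
Points give the median log2 ratio of drought over normal (horizontal axis) of each fixed locus list (vertical axis) in ZH11, the mutant and the overexpressor, 1 pair of libraries per genotype. The LEA list stands at 9.52, 9.32 and 8.26 and the photosynthesis list at -5.25, -4.93 and -3.92.

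Drought ratios are given here genotype by genotype; these differences had 1 library each and were not tested. The drought library labelled overexpressor had 0.954 of the OsbZIP23 level of ZH11 drought, so its ratios do not compare a raised level under drought. The clade A PP2C list had a median drought ratio of 4.18 in ZH11, 3.70 in the mutant and 2.29 in the overexpressor. The ABA synthesis list had 1.4, 1.82 and -0.40 in the same order. The stress transcription factors had 2.74, 4.75 and 2.69, and the senescence genes 3.95, 4.73 and 3.00. Gene by gene, the stress transcription factors' drought ratio was lower in the overexpressor than in ZH11 by a median difference of -1.42, with 11 of 18 members at least 2-fold lower, and the mutant's median difference was 0.59. Ribosomal protein genes had medians of -1.03 in ZH11, -1.26 in the mutant and -0.10 in the overexpressor, where 157 of 348 were higher under drought. At least 2-fold apart were 11431 genes in ZH11, 12422 in the mutant and 8449 in the overexpressor. Over the genes that changed with drought, the median absolute log2 ratio was 1.87, 1.96 and 1.35. Among single genes, the cold and drought factor OsDREB1A had a drought ratio of 5.79 in the mutant and 0.41 in ZH11, and laccase 7 (LOC_Os01g63190), a lignin enzyme, 2.12 and -3.82. In the overexpressor, a xyloglucan hydrolase of the cell wall (LOC_Os06g48200) had -0.72 against -6.02 in ZH11, and a receptor kinase (LOC_Os11g44750) had 3.59 log2 less than in ZH11.

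The mutant comparison sets the mutant libraries against ZH11 over both conditions. In edgeR 3 genes were higher and 0 lower than in ZH11; 779 had an unadjusted p under 0.05, and DESeq2 called 81, 74 higher and 7 lower. LOC_Os07g06834, without a description, had 3 reads over the ZH11 libraries and 363-fold more in the mutant (124–1766), a log2 fold change of 8.35 (SE 0.41, adjusted p = 0.0201). LOC_Os08g14195, without a description, was 122-fold higher (69.8–237), at 6.87 (SE 0.46, adjusted p = 0.0394). The third was LOC_Os12g24050, described among DNA and RNA polymerases and named after its values were seen, at 6.51 (SE 0.43, adjusted p = 0.0394). All 3 were higher in the mutant in 2 of 2 conditions, which the naming rule had required of the first 2. All 3 also passed in the overexpressor and are among 11 genes at least 8-fold lower in both ZH11 libraries than in both other lines, so they set ZH11 apart and not the mutant alone. No member of a fixed list passed over all genes. Values that did not pass included a glycosyl hydrolase of cell walls (LOC_Os09g36350) at -5.70 (SE 0.59, adjusted p = 0.121), and the seed maturation genes LOC_Os03g06360 at -3.08 and LOC_Os06g23350 at -2.15. Without the ZH11 normal or the ZH11 drought library 0 genes passed; without mutant normal, mutant drought, overexpressor normal and overexpressor drought there were 6, 42, 70 and 185. With DESeq2 size factors LOC_Os08g14195 had an adjusted p of 0.051; over the alternatives its adjusted p reached 1.00, without the stress term.

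By list, LEA genes had a median of -0.17 in the mutant (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.507) and clade A PP2C genes -0.14 (camera adjusted p = 0.280). Camera called 5 lists, each with adjusted p = 0.989 with an estimated correlation. WRKY factors, many of which act in defence, had a median of 0.41 (adjusted p = 0.00161), NAC factors 0.23 (adjusted p = 0.0192), heat shock proteins 0.22 (adjusted p = 0.0192) and glutathione S-transferases 0.21 (adjusted p = 0.0152). Genes described as chlorophyll a/b binding had -0.62 (adjusted p = 0.0152). For the other 22 lists the adjusted p was at least 0.261. Median, mean and test differed in sign for AP2/ERF (0.23, -0.04, upward), PP2C of all clades (0.01, -0.04, downward) and bZIP factors by description (0.04, -0.06, upward); the last 2 medians changed sign under another scaling. The WRKY list did not pass without mutant drought (adjusted p = 0.823), nor NAC without ZH11 drought (0.101) or mutant drought (0.179), heat shock proteins without ZH11 normal (0.862) or mutant drought (0.493), glutathione S-transferases without ZH11 drought (0.542) or mutant drought (0.309), or chlorophyll a/b binding without ZH11 drought (0.166) or mutant drought (0.179). Without ZH11 normal, clade A PP2C (adjusted p = 2.0e-04), LEA (0.00984) and ribosomal proteins (0.00119) passed. Without mutant drought, the lists gained included ribosomal proteins, LEA by description and expansins. Photosynthesis and expansins were gained without ZH11 drought. The lists gained without mutant normal included stress transcription factors. Each of these fits left the mutant or ZH11 with 1 library.

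In single libraries of the mutant and ZH11, 567 genes were at least 2-fold higher and 709 lower under normal growth, and 1014 higher and 1075 lower under drought. With total count scaling these were 703 and 587, and 649 and 1465; with a pseudocount of 2 they were 369 and 310, and 688 and 344, so which side was larger depended on the setting. Under normal growth a prolyl oligopeptidase (LOC_Os04g47360) was 36.2-fold higher (29.9–44.3) and laccase 7 (LOC_Os01g63190) had 4.94 CPM against 200.7 CPM. Under drought a receptor kinase (LOC_Os04g56430) was 28.5-fold higher (24.7–33.0) and seed maturation gene LOC_Os03g06360 had a ratio of 0.088 (0.051–0.141). Under drought the LEA median was -0.24, at percentile 0.60 of matched random lists, and the PP2C median -0.24, at percentile 1.87; under normal growth they were 0.00 (percentile 32.6) and -0.08 (16.1). The WRKY and NAC medians were 0.44 and 0.52 under drought, and -0.01 (percentile 34.9) and -0.01 (41.6) under normal growth.

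The overexpressor comparison sets the libraries labelled overexpressor against ZH11 over both conditions. OsbZIP23 was 40.8-fold the ZH11 level in the normal library and 0.954 of it in the drought library, so only the normal pair compares a raised level of OsbZIP23 with ZH11. In edgeR 4 genes were higher and 0 lower than in ZH11; 1104 had an unadjusted p under 0.05, and DESeq2 called 63, 42 higher and 21 lower. LOC_Os03g02470, without a description, had 1 read over the ZH11 libraries and 860-fold more in the overexpressor (154–34018), at 9.43 (SE 0.58, adjusted p = 0.0315). LOC_Os07g06834 was 397-fold higher (135–1926), at 8.50 (SE 0.41, adjusted p = 0.0181), and LOC_Os08g14195 146-fold (83.1–282), at 7.08 (SE 0.46, adjusted p = 0.0315). LOC_Os12g24050, of polymerase type, was the fourth, at 6.25 (SE 0.42, adjusted p = 0.0315). Values that did not pass included a peroxidase (LOC_Os07g48020) at -5.90 (SE 1.20, adjusted p = 0.644), a formin of the actin skeleton (LOC_Os10g02980) at -4.17 (SE 0.89, adjusted p = 0.650) and a ribonuclease T2 (LOC_Os09g36700) at 5.31 (SE 1.13, adjusted p = 0.650). Both genotype comparisons rest on the same ZH11 libraries, so genes named in both are not independent findings; 3 of the 4 are among the 11 genes low in ZH11 alone, and LOC_Os03g02470 is not. Without the ZH11 normal or the ZH11 drought library 0 genes passed; without mutant normal, mutant drought, overexpressor normal and overexpressor drought there were 26, 35, 422 and 45.

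Camera called 9 lists in the overexpressor, and no member of a fixed list passed over all genes. Photosynthesis genes had a median of 0.85 (adjusted p = 4.0e-05; adjusted p = 0.643 with an estimated correlation) and genes described as chlorophyll a/b binding 0.62 (adjusted p = 0.00459; adjusted p = 0.643 with an estimated correlation). Senescence genes had -1.26 (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.00144; adjusted p = 0.643 with an estimated correlation). Heat shock proteins had -0.43 (adjusted p = 1.1e-06; adjusted p = 0.654 with an estimated correlation). WRKY factors had -0.51 (0 higher and 1 lower adjusted over the list alone; adjusted p = 1.2e-08; adjusted p = 0.643 with an estimated correlation). NAC factors had -0.30 (adjusted p = 4.0e-04; adjusted p = 0.704 with an estimated correlation). bZIP factors had -0.21 (adjusted p = 0.0247) and glutathione S-transferases -0.34 (adjusted p = 0.00369), each with adjusted p = 0.643 with an estimated correlation. Ribosomal proteins had 0.30 (adjusted p = 6.9e-07; adjusted p = 0.730 with an estimated correlation); without the overexpressor drought library this list was called in the other direction (adjusted p = 0.0042). Stress transcription factors had 1 lower gene adjusted over the list alone (camera adjusted p = 0.106). For the other 18 lists the adjusted p was at least 0.0645. Median, mean and test differed in sign for ABA synthesis (-0.17, 0.06, downward), clade A PP2C (-0.13, 0.21, upward), LEA (-0.13, -0.09, upward), proline, trehalose and raffinose (0.15, -0.06, downward), antioxidants (-0.12, 0.07, downward) and housekeeping genes (0.00, 0.00, downward), whose median changed sign under another scaling. Calls were lost without overexpressor drought for heat shock proteins (adjusted p = 0.931), WRKY (0.0877), NAC (0.955) and bZIP factors (0.668), without ZH11 drought for photosynthesis (0.0645), without ZH11 normal for chlorophyll a/b binding (0.166), bZIP factors (0.0781) and glutathione S-transferases (0.166), and without overexpressor normal for chlorophyll a/b binding (0.0859) and glutathione S-transferases (0.145). Without overexpressor drought, which left 1 overexpressor library, the lists gained included clade A PP2C, LEA and ABA hydroxylases. Without overexpressor normal, which also left 1, the lists gained included ABA synthesis, ABF-type factors, stress transcription factors and LEA by description. Without ZH11 drought, clade A PP2C (0.00537), P450 (0.00938) and AP2/ERF (0.0416) passed, without mutant normal P450 (0.0224) and AP2/ERF (0.0424), and without mutant drought AP2/ERF (0.0447).

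In single libraries, the medians of some ABA-related lists against ZH11 lay on opposite sides of 0 under the 2 conditions, and others did not. Under normal growth the overexpressor's median against ZH11 was 0.50 for clade A PP2C genes (percentile 99.9 of matched random lists), 0.40 for ABA synthesis (99.7), 0.47 for LEA genes (100.0) and 0.60 for ABA hydroxylases (99.6). Under drought it was -0.65 for clade A PP2C genes (percentile 10.1), -0.95 for ABA synthesis (0.40), -0.48 for LEA genes (24.1), -0.82 for stress transcription factors (0.01), and 0.61 for ABA hydroxylases (93.7). SnRK2 kinases had 0.13 under both conditions, and ABA receptors 0.03 and 0.20. Photosynthesis genes had 1.41 and senescence genes -1.54 under drought, and 0.19 (percentile 88.9) and -0.86 (0.43) under normal growth. Random lists were matched on mean CPM over all RNA libraries. Lists low in 1 condition, such as LEA genes under normal growth, were therefore ranked among genes with more reads there. Their percentiles in that condition may be too extreme. At least 2-fold apart were 379 genes higher and 688 lower under normal growth. Under drought there were 2125 higher and 1591 lower; with DESeq2 size factors these were 1761 and 2032, and with total count scaling 2957 and 1030, so which side was larger depended on scaling. Under normal growth the peroxidase LOC_Os07g48020 was 77.4-fold lower (ratio 0.013, 0.0076–0.020). Under drought the ribonuclease T2 LOC_Os09g36700 was 64.1-fold higher (45.3–94.1) and small heat shock protein LOC_Os03g16030 had a ratio of 0.137 (0.127–0.149).

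The peak lists ask where OsbZIP23 sits on chromatin and whether that differs with drought or with a raised level of the factor. The lists held 1738 peaks for ZH11 normal, 4260 for ZH11 drought and 11611 for overexpressor normal, covering 2.46, 6.60 and 15.5 Mb. Peaks held 1.27%, 4.32% and 16% of the tags used. Median fold enrichment was 6.09 (quartiles 4.91–9.21), 6.34 (5.05–8.29) and 8.85 (6.84–12.1), and median widths were 1178.5, 1341 and 1148 bp. A fold enrichment of at least 10 was reached by 382, 647 and 4565 peaks. The genome size in the header gives a mean background 7.22 times lower than the span of the peaks does. With the background of each peak raised at least to the mean over the span, 415, 2447 and 10263 peaks stayed above the caller's cutoff. This raised the background of 86.8%, 50.8% and 19.9% of the peaks, and left that of the rest as it was. The 5 peaks with the highest enrichment in each list lay on chromosomes 4, 5, 10 and 11, and each was present in all 3 lists. The highest in ZH11 normal was at chromosome 11, positions 12164506 to 12164805, with fold 63.5. The same place had fold 69.2 in ZH11 drought (12164529 to 12164784) and 66.7 in overexpressor normal (12164522 to 12164791). Chromosome 5 had a peak at 29907676 to 29908055 with fold 57.1 in ZH11 normal, and 64.9 and 60.3 in the other lists. Folds at these 2 places were similar in the 3 lists. Without a control library, OsbZIP23 binding there cannot be told apart from another local excess of tags. Genes at these places were not analysed here.

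**Figure D3:**
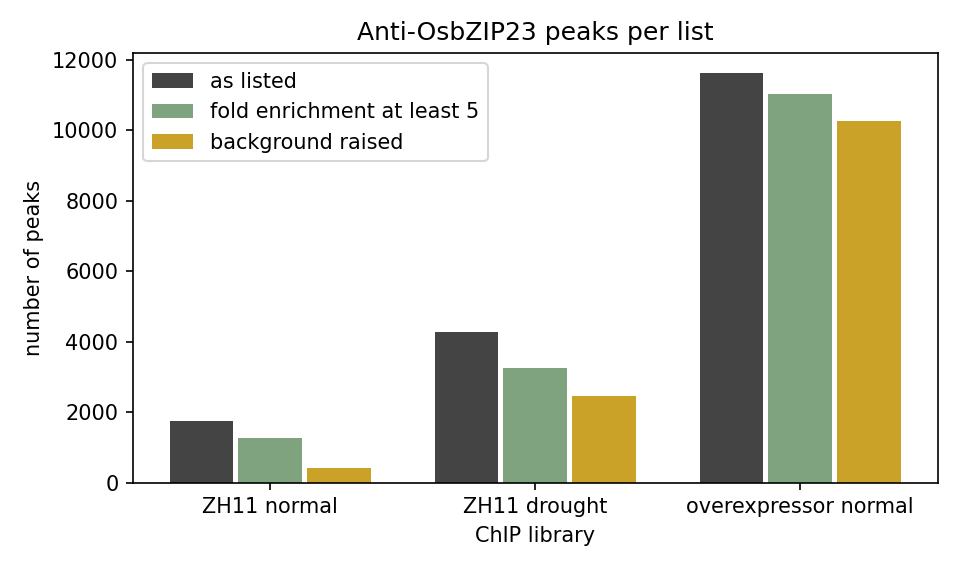
Bars give the number of OsbZIP23 peaks (vertical axis, from 0) in each of the 3 ChIP libraries, as listed, at a fold enrichment of at least 5, and with the background raised. The lists hold 1738, 4260 and 11611 peaks, and 415, 2447 and 10263 with the background raised.

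Of the ZH11 normal peaks, 42.6% (40.3–45.0) overlapped a ZH11 drought peak, where random placement gave 3.30%. They overlapped an overexpressor peak in 40.0% (37.7–42.3; random 8.07%), and 448 of them (25.8%) overlapped both other lists. Of the ZH11 drought peaks, 58.9% (57.4–60.4) overlapped an overexpressor peak (random 8.98%). Among the drought peaks, 3508 did not overlap a ZH11 normal peak, and 2049 of these (58.4%) overlapped an overexpressor peak, as did 460 of the 752 drought peaks (61.2%) that overlapped a ZH11 normal peak. Peaks found in no other list made up 43.2% of ZH11 normal, 34.2% of ZH11 drought and 75.6% of overexpressor normal. With the raised background, ZH11 drought peaks overlapped an overexpressor peak in 81.3% and ZH11 normal peaks overlapped a ZH11 drought peak in 58.6%. Random placement took every position of a chromosome as equally likely, and there was no control library. Overlap above random placement therefore cannot tell shared OsbZIP23 binding from another local excess of tags common to the libraries.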

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

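Of the tests in this part, the thinning of drought tags was chosen before its result was seen, and the other tests were chosen afterwards. The genes named next stand out because their drought ratio went opposite ways in 2 genotypes, by at least 2-fold each way and with at least 50 reads. With 1 library per group, none of these differences was tested.

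OsbZIP23 (LOC_Os02g52780) had a drought log2 ratio of -1.53 in the overexpressor, 3.86 in ZH11 and 3.68 in the mutant, differences of -5.40 and -5.22. OsDREB1A, a factor of cold and drought responses, had -2.62 in the overexpressor and 5.79 in the mutant (difference -8.40). The ABA synthesis gene OsNCED5 had -1.49 in the overexpressor, 1.41 in ZH11 and 2.47 in the mutant (differences -2.91 and -3.96). Rubisco activase (Rca) had -1.29 in the overexpressor and 1.25 in the mutant (difference -2.53). Laccase 7 (LOC_Os01g63190) had 2.12 in the mutant, -3.82 in ZH11 and -1.82 in the overexpressor; mutant minus ZH11 was 5.94 and overexpressor minus mutant -3.95. A phosphoenolpyruvate carboxylase (LOC_Os12g08760) had -1.38 in the overexpressor and 4.90 in the mutant (difference -6.28). The ribonuclease T2 gene LOC_Os09g36700 had 3.00 in the overexpressor and -1.52 in the mutant (difference 4.52). The cupin gene LOC_Os03g10110 had 3.21 in the overexpressor and -1.77 in ZH11 (difference 4.98). A transporter of the pleiotropic drug resistance type (LOC_Os01g24010) had -1.79 in the mutant, 2.69 in ZH11 and 2.17 in the overexpressor (mutant minus ZH11 -4.48, overexpressor minus mutant 3.96). Phosphoribosyl pyrophosphate synthase 3 (LOC_Os01g52530) had -1.33, 2.48 and 1.92 in the same order (-3.81 and 3.25). A pyridoxal phosphate-dependent transferase (LOC_Os08g04560) had -1.75, 2.05 and 1.85 (-3.80 and 3.6).

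The libraries labelled overexpressor had smaller drought ratios than ZH11, with medians of 1.35 and 1.87 over the genes that changed, and OsbZIP23 did not exceed ZH11 in the drought library. Unstressed tissue mixed into that library is argued against for the smaller rise: 186 strongly falling genes leave room for a median share of 8.95%, enough to lower risers by 0.14 log2, while 5579 risers were lower than in ZH11 by a median of 0.48 (0.12 and 0.27 under total count scaling); for the smaller fall it stays open, since shares implied by single falling genes spread 4.27-fold between quartiles, which single samples may give with or without mixing. A scaling factor moves risers and fallers the same way: total count scaling took the risers' gap to ZH11 from 0.47 to 0.28 and the fallers' gap from 0.57 to 0.73, so the size of the risers' gap depends on scaling, while the 3 scalings tried argue against it for both gaps together (the median absolute gap, which responds little to such a shift, stayed at 0.52 or more). For a ZH11 or mutant library under this label, a first rule picked 0 genes and decided nothing; a wider rule chosen after that picked 9 genes at least 8-fold apart in the normal overexpressor library, and 66.7% of them lay on the same side in its drought library, 5 of 5 higher and 1 of 4 lower, which argues against it. A weaker response in that genotype and an earlier stage of drought in that sample may both give the pattern, and were not tested, since each genotype and condition had 1 library.

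The lists held 1738 peaks for ZH11 normal, 4260 for ZH11 drought and 11611 for overexpressor normal. The genome size in the headers is argued against as the reason for the larger overexpressor list: with the background raised, its ratio to ZH11 normal went from 6.68 to 24.7. More tags in the drought library are argued against for the larger drought list: thinned to the normal number of tags, 3218 of 4260 peaks still passed (3160–3278 over 100 draws), against 1738. Tag density at peaks found in all 3 lists was 1.5 times that of ZH11 normal in the overexpressor, so the efficiency of a single precipitation and a raised level of the factor cannot be told apart with 1 library each.

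The genes LOC_Os07g06834 and LOC_Os03g43100 had at most 3 reads over the ZH11 libraries and at least 93 in each library of the other lines. With 1 gene absent from the mutant alone and 0 from the overexpressor alone, neither that ratio of 2 nor the 0% of these genes with the other within 30 loci decides anything; the ratio was first read as a fit to chance, and that reading was withdrawn. A wider rule, chosen after the genes were seen, took genes at least 8-fold lower in both libraries of a line than in the others. It gave 11 genes for ZH11, 1 for the mutant and 0 for the overexpressor (6, 0 and 0 at 16-fold). This ratio of 11 decides nothing about chance of the lowest line. The rule followed sight of such genes, all 11 rest on the same ZH11 libraries, and some of them are neighbours. Genes at least 8-fold higher in both libraries of a line numbered 0 for ZH11, 1 for the mutant and 2 for the overexpressor. Of the 11 genes, 36.4% had another within 30 loci, where 1000 random sets gave a mean of 3.08% and 12 of them reached 36.4%. The rule, written after the 11 genes and their neighbouring positions had been seen, asked for more than every random set and counted this tie against a difference between seed stocks; after the tie was seen this was changed to undecided, since genes that lie apart do not exclude such a difference and neighbouring genes do not prove it.

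For the genes changed under drought, the real split of the 6 libraries gave 11475 calls and the highest of the others 0. This decides nothing. The other splits leave much of the drought difference in the residual, which largely fixed their lack of calls in advance. The 10 splits are also too few for a share under 0.05.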

How the results depend on the processing

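Leaving out both overexpressor libraries and raising the peak background were chosen after the data were seen; the other alternatives were planned. Of the values for named genes, 475 stayed on the same side of the threshold in the same direction, 115 gained and 16 lost a call, and 2 moved. Of the list values 564 stayed, 57 moved, 46 lost and 34 gained a call, and 1 reversed. Of single ratios 60 stayed and 34 moved. Except where its construction shows it, the cause was not tested.

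Genes changed under drought ran from 4898 to 13787 when 1 library was left out, and stayed within 1.5 times 11475 under the other alternatives. In the mutant, 3 genes passed, against 1 with DESeq2 size factors, 9 with total count scaling, 184 without a filter on low counts, 81 with the DESeq2 test, 0 without the stress term, 129 without both overexpressor libraries and from 0 to 185 without 1 library. In the overexpressor, 4 passed, against 12 with total count scaling, 158 without a filter, 63 with DESeq2, 0 without the stress term and from 0 to 422 without 1 library. Lists called by camera went from 12, 5 and 9 for drought, mutant and overexpressor to 0, 0 and 0 with an estimated correlation. With 2 residual degrees of freedom that repeat could hardly call a list, so its lack of calls decides little. The ribosomal list reversed in the overexpressor without its drought library (adjusted p = 0.0042), and without other single libraries its adjusted p ran from 1.5e-18 to 0.011.

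With a pseudocount of 2, which pulls ratios of low counts towards 1, genes at least 2-fold apart numbered 679 and 1032 in the mutant under normal growth and drought, and 515 and 2170 in the overexpressor. With at least 50 counts, 1251 differed in the mutant under drought. The 1000 highest-scoring peaks gave 1000 per list by construction, and the raised background left 415 for ZH11 normal and 2447 for ZH11 drought. Shares are given in the order ZH11 normal in ZH11 drought, ZH11 normal in overexpressor and ZH11 drought in overexpressor. They were 39.2%, 37.6% and 57.2% when 0.5 of the shorter peak had to overlap, 18.4%, 18.8% and 39.9% with summits within 100 bp, and 58.6%, 66.5% and 81.3% with the raised background. At a fold enrichment of at least 5 the last was 61.1%. Alternatives for promoter peaks, motifs and bound genes were not run, since these results were not. At the depth, common dispersion and 1 library per group of these data, 6% of genes changed 2-fold between genotypes were recovered in simulation. Which of these limits it was not tested. That simulation had no drought effect and no spread of dispersion between genes, so recovery in the real data may differ.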

Other observations

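The genes in this part were chosen after their values were seen. At the places known for clusters of diterpenoid phytoalexin synthesis, which make antimicrobial compounds, 6 of 9 genes on chromosome 2 and 5 of 5 on chromosome 4 were at least 2-fold higher in the mutant than in ZH11 under normal growth, and 0 were 2-fold lower. These are not a fixed list, no enrichment was tested, and the genes printed here are mostly those with large differences. The terpenoid cyclase LOC_Os04g09900 had 38.7 CPM in ZH11, 320.5 in the mutant and 17.3 in the overexpressor under normal growth, and at most 0.280 CPM in each drought library. Its neighbours LOC_Os04g10010 and LOC_Os04g10000, of the dehydrogenase type, had 6.90, 108 and 4.47 CPM and 8.0, 79.2 and 3.89 CPM in the same order. On chromosome 2 the terpenoid cyclases LOC_Os02g36140 and LOC_Os02g36210 had 5.14, 125 and 3.94 CPM and 31.5, 203 and 19.8 CPM. The cytochromes P450 LOC_Os02g36070 and LOC_Os02g36190 had 3.31, 88.8 and 0.663 CPM and 15.8, 135 and 4.97 CPM. The 3 others on chromosome 2 were LOC_Os02g36220 and LOC_Os02g36264, with log2 ratios of -0.48 and -0.36, and LOC_Os02g36150, with 0.80. Under drought, LOC_Os04g09900 and LOC_Os02g36210 had log2 fold changes of -8.27 and -8.31, both past the test. The mutant ratios rest on 1 library per group. In the genotype fit over both conditions none of the cluster genes passed in the mutant; the lowest adjusted p was 0.370, for LOC_Os02g36280.

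Among the genes at least 8-fold higher in the overexpressor than in both other normal libraries were 2 described as plant transposases. LOC_Os02g03640 had 174.5 reads in the overexpressor, 9 in ZH11 and 20 in the mutant under normal growth, and LOC_Os07g11150 had 291.5, 20.5 and 7. A cytochrome P450 of family 72 (LOC_Os01g43740) had 347.5, 19 and 41 reads. Under drought LOC_Os01g43740 had 652 reads in the overexpressor, 136 in ZH11 and 48 in the mutant. In the genotype fit LOC_Os02g03640, LOC_Os07g11150 and LOC_Os01g43740 did not pass in the overexpressor (adjusted p = 0.377, 0.0788 and 0.511). All 3 are also among the 9 genes used above on the label of the overexpressor drought library, so they are not a separate finding.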
